A study of Mus musculus with 5 samples.

How the data were processed

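RNA from livers of female BALB/c mice was pooled by the study's authors, 6 animals to a pool and 1 pool to a group, labelled with Cy3 and hybridised to Agilent mouse gene expression arrays, 1 array per group and all 5 on 1 slide. The deposited array files give the processed signal of each spot as an intensity, background-subtracted and detrended by Agilent Feature Extraction 12.0.3.1 per the file headers and not scaled between arrays. Spots near background carry a surrogate value per the file headers. The deposited value table holds log2 values, equal to the log2 processed signal plus 1 constant per array that brings the 75th percentiles to one level. Its column medians were 4.02 for vehicle, 4.01 for TGZ, 4.07 for BSO plus TGZ, 4.00 for RGZ and 3.92 for BSO plus RGZ, so it was scaled and not centred per gene. The software of that scaling is not given in the sources used here. The names troglitazone, rosiglitazone and buthionine sulfoximine for the labels' abbreviations are taken from the study's title and from general knowledge.

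Each array had 59305 non-control spots for 56605 probes. The 75th percentile of the processed signal was 184.5 for vehicle, 141.5 for TGZ, 169.8 for BSO plus TGZ, 208.4 for RGZ and 191.2 for BSO plus RGZ. No spot was flagged as saturated. Before scaling, however, the Saa1 and Saa2 signals of every treated group lay above the brightest spike-in RNA. The spike-in RNA does not show whether signal stayed proportional there, so the folds of these genes could be lower bounds. Of the probes, 300 were printed in 10 spots each, and the median SD of their log2 signal within an array was 0.040 to 0.043. Spots of a probe were averaged, log2 values were taken, and the 75th percentile of the array's non-control probes was subtracted. A gene was represented by the probe with the highest mean over the 5 arrays. The arrays carry 36870 gene names, 24146 of them symbols of the RefSeq table. Of all gene names, 22331 were well above background on at least 1 array and 18483 on all 5, by the scanner software's call. Coordinates are mm9 as the file headers give them and were not converted. Probes of related genes, among them the Saa, Hsd3b, Mup and histone genes, can share sequence.

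The difference between groups is the difference of scaled log2 signal. Its measurement error combines the Feature Extraction error of both spots, with a median SD of 0.20 to 0.21 on the log2 scale, so a typical 95% interval spans a factor of 1.32 either way. The error is the software's own estimate, with a median SD of 0.145 on each array, and is larger than the SD of replicate spots. This error does not cover differences between animals, pools or labelling reactions, and with 1 array per group differences between groups were not tested. A gene was counted when it differed by at least 2-fold. Where the gene was well above background on only 1 of the arrays compared, the floor of the dim array (the lowest signal on it that was called well above background) was used in place of a value below it, and the difference is a bound written "at least". In 1 to 17 of the bounds past 2-fold per comparison another probe of the gene was above background on the dim array, and no such gene is named. The rule for named genes, fixed before the data were examined, took for each comparison the 8 largest measured differences in each direction with every other well measured probe in the same direction and a proper gene symbol, the 2 largest bounds in each direction, members of the gene lists with up to 4 examples per list from those farthest from 0, and the 8 largest differences in each direction between the BSO effects. The text describes part of these in rank order, and 1 gene among them is not reported here. The plot of single genes shows genes that the rule names in at least 1 comparison.

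Gene lists of pathways, stress responses and cell types, 30 in number with 466 genes, were also fixed before the data were examined. Of the genes 464 matched a name on the array, 1 of them through a RefSeq synonym. A list needs at least 4 measured members. Its median log2 difference was compared with 10000 random lists matched on expression in 20 bins. A list was said to stand apart, higher or lower, when less than 0.5% of the random lists had a higher, or less than 0.5% a lower, median. About 0.3 of 30 lists per comparison would do so if the genes of a list varied independently, and 10 to 15 did. Genes of a pathway or cell type can vary together between any pools, which the random lists leave out. The 0.3 is therefore not the chance rate of these lists. The percentile describes the list against other genes of these arrays and carries no information on repeat animals. Against vehicle, 9 lists were higher and 5 lower with TGZ, 10 and 5 with BSO plus TGZ, 7 and 6 with RGZ, and 8 and 6 with BSO plus RGZ. Correlations between differences were computed across 18483 genes. Where both differences use the vehicle array, 100 sets of unchanged groups were simulated with the arrays' measurement error. They give the value that shared spot measurement error alone produces. Deviations of the vehicle pool and its labelling also enter both differences and are left out of the simulation. In data simulated for TGZ against vehicle, 96% of 100 genes changed by 1.5 on the log2 scale and all of 100 genes changed by 2.5 passed 2-fold, and 9 of 18789 unchanged genes did.

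Alternatives fixed beforehand were normexp background correction of the mean signal with an offset of 50, median scaling, quantile normalization, no filter on dim probes, only genes well above background on all 5 arrays, the submitters' stated probe filter, the mean over a gene's probes, a size rule of 2-fold and more than 3 times the measurement error, the deposited log2 table, the mean in place of the median of a list, and only the genes above the median of mean signal for correlations. The submitters' filter as labelled asks for a value of 0 in the flag for positive and significant signal. It was applied with the value 1. Scaling to the spike-in RNA was added after the data were seen. The work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1. Gene set enrichment tools that need replicates were not used.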

Results

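Gene expression was measured in livers of 6-week-old female BALB/c mice, collected 6 hr after an intraperitoneal dose. The groups were vehicle, troglitazone (TGZ) at 300 mg/kg, TGZ with buthionine sulfoximine (BSO) at 700 mg/kg, rosiglitazone (RGZ) at 300 mg/kg, and RGZ with BSO at 700 mg/kg. TGZ and RGZ are thiazolidinediones, which activate the nuclear receptor PPAR gamma, and the study's title concerns liver injury caused by TGZ. BSO blocks glutathione synthesis. Each group was 1 pool of RNA from 6 livers on 1 single-colour array, so no group had a replicate, and the number of arrays limits the precision of every value. Intervals given with folds are 95% intervals of spot measurement error as the scanner software estimates it, and do not cover variation between animals. Between 51.9% and 55.1% of the 56605 probes were well above background on each array, and 18483 genes were well above background on all 5 arrays. Log2 signals of the arrays correlated across probes with r from 0.951 (vehicle and TGZ) to 0.995 (RGZ and BSO plus RGZ). No group received BSO alone. Every comparison with vehicle uses the same vehicle array, so a direction shared by several treated groups is not an independent repeat.

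The comparison of TGZ with vehicle asks what the compound did to the liver transcriptome within 6 hr. Cd14, a co-receptor for bacterial lipopolysaccharide, was 246-fold higher with TGZ (interval 186 to 326) and the stress transcription factor Atf3 122-fold higher (82.2 to 182). Arid5a, an RNA-binding regulator of inflammatory transcripts, was 120-fold higher, the serum amyloid genes Saa1 and Saa2 were 115-fold and 105-fold higher, and the chemokine receptor gene Ccr8 was 95.9-fold higher. Pdk4, a kinase that shuts off pyruvate oxidation, was 94.9-fold higher. Il1r2, the decoy receptor of interleukin 1, and Thbs1, thrombospondin 1, were not well above background with vehicle and were at least 97.1-fold and at least 50.9-fold higher. In the other direction, Fam89a was 35.8-fold lower (26.3 to 48.7), Dclk3 27.3-fold, the endoplasmic reticulum degradation factor Derl3 22.5-fold and Anks4b 22.3-fold lower. Hdhd3 was 21.2-fold lower, Wnt5b 20.2-fold, Fam13a 19.1-fold, and Fasn, which encodes fatty acid synthase, 18.8-fold lower (14.2 to 24.8). Cyp7a1, the rate-limiting enzyme of bile acid synthesis, and the fractalkine receptor gene Cx3cr1 were not well above background with TGZ and were at least 63.1-fold and at least 26-fold lower. The Cd14 probe lies on chromosome 18 at 36884727 to 36884786 and the Fasn probe on chromosome 11 at 120668460 to 120668519 (mouse build mm9).

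In total 2147 genes were at least 2-fold higher and 2020 at least 2-fold lower with TGZ than with vehicle, together 19.6% of the genes with a value. Of these, 646 and 434 differed by at least 4-fold. Spot measurement error alone would give about 7.8 genes past 2-fold. The counts depend on how arrays were scaled and background was removed: normexp background correction gave 1104 higher and 909 lower, and scaling to the spike-in RNA gave 1210 higher and 4249 lower.

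Lists of stress and growth signalling genes went both ways with TGZ. Of 17 measured immediate early genes, the fast transcriptional responders to growth and stress signals, 15 were at least 2-fold higher and none lower, with a median log2 difference of 2.83. Btg2 was 83.6-fold higher, Nr4a1 47.4-fold, Ier3 42.5-fold and Fos 16.4-fold. Of 18 genes of the integrated stress response, 11 were higher and none lower (median 1.62). Among them were Chac1, which degrades glutathione, at 33.4-fold, Ddit4, an inhibitor of mTORC1, at 16.6-fold and the secreted stress factor Gdf15 at 9.87-fold. Of 19 p53 targets and DNA damage genes, 7 were higher and 1 lower (median 0.59). Cdkn1a, the cell cycle inhibitor p21, was 82.8-fold higher, Gadd45g 16.6-fold and Trp53inp1 15.3-fold. Endoplasmic reticulum chaperones were lower as a list (median -0.52), with 3 of 16 higher and 3 lower. Sdf2l1 was 3.49-fold and Pdia4 2.54-fold lower, while Dnajb9 was 3.03-fold higher. With the mean in place of the median (-0.33, percentile 0.5) that list lay at the cut-off and was not called.

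Inflammatory genes were higher as well. Of 21 acute phase proteins, 17 were at least 2-fold higher and none lower (median 2.53), with Lcn2, an iron-sequestering lipocalin, at 89.1-fold and the metalloreductase Steap4 at 23.0-fold. Of 17 measured cytokine and chemokine genes, 11 were higher and none lower (median 1.49). The interleukin 1 receptor antagonist Il1rn was 62.5-fold, the cytokine signalling inhibitor Socs3 48.7-fold and the neutrophil chemoattractant Cxcl1 44.3-fold higher. Neutrophil markers were higher beside them, with 8 of 13 past 2-fold (median 1.56). Retnlg was 42.3-fold, S100a8 18.6-fold and S100a9 16.8-fold higher. The neutrophil list no longer stood apart when only genes well above background on all 5 arrays were kept (median 0.54, percentile 98.75) or with the submitters' filter (percentile 98.56). Interferon-stimulated genes were lower as a list (median -0.63), with 2 of 16 at least 2-fold lower and 1 higher. Psmb9 was 3.86-fold and Ifit1 2.21-fold lower (-0.67 on the log2 scale with normexp), and Rsad2 4.01-fold higher. With the mean in place of the median that list no longer stood apart (mean -0.29, percentile 12.08).

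The lists of cholesterol synthesis, fatty acid synthesis and bile acid genes were lower with TGZ, and those of PPAR targets higher. Of 19 cholesterol synthesis genes, 16 were at least 2-fold lower and none higher (median -2.39). Mvd was 10.8-fold, Hmgcs1 8.17-fold, Fdps 7.21-fold and Idi1 6.36-fold lower. Of 14 fatty acid synthesis genes, 7 were lower and 1 higher (median -1.13). Besides Fasn, the lipogenic transcription factor gene Srebf1 was 4.96-fold lower and Acss2 3.83-fold lower. Scd1, which desaturates fatty acids, was 4.48-fold higher. Of 16 bile acid genes, 4 were lower and none higher (median -0.41). The repressor gene Nr0b2 was 11.8-fold and the transporter gene Slco1a1 2.97-fold lower. Of 15 PPAR gamma targets and lipid droplet genes, 7 were higher and 1 lower (median 0.93). Cidec and Plin4, which coat lipid droplets, were 53.6-fold and 31.3-fold higher, and the fatty acid carrier gene Fabp4 was 6.06-fold higher. PPAR alpha targets and fatty acid oxidation genes had a median of 0.41, with 7 of 24 higher and 1 lower. Ucp3 was 3.32-fold and Cpt1b 3.24-fold higher. The PPAR alpha median was -0.04 with spike-in scaling, and its list no longer stood apart with the mean over each gene's probes (median 0.34, percentile 98.91). Of 12 gluconeogenesis and glucocorticoid target genes, 7 were higher and 2 lower (median 1.37). Igfbp1, the binding protein of insulin-like growth factors, was 57.4-fold and the insulin receptor substrate gene Irs2 10.4-fold higher. G6pc, the catalytic subunit of glucose-6-phosphatase, was 13.1-fold lower and Tsc22d3, a glucocorticoid-induced gene, 9.22-fold lower.

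The antioxidant genes controlled by NRF2 did not stand apart as a list with TGZ (median 0.05), with 4 of 20 higher and 1 lower. Hmox1, heme oxygenase 1, was 18.8-fold higher and Srxn1, sulfiredoxin 1, 4.86-fold higher, while Osgin1 was 3.85-fold lower. Genes of glutathione synthesis and sulfur amino acids had a median of 0.08. Chac2, a glutathione-degrading enzyme like Chac1, was 8.38-fold lower. Circadian clock genes also went both ways (median -0.02, 3 of 14 higher and 5 lower). Dbp was 16.4-fold and Hlf 6.80-fold lower, and Nfil3, a repressor that acts at the same sites, was 7.73-fold higher. Hepatocyte secreted and metabolic genes (median 0.15) and mitochondrial respiratory chain genes (median 0.17) had no member past 2-fold.

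**Figure D1:**
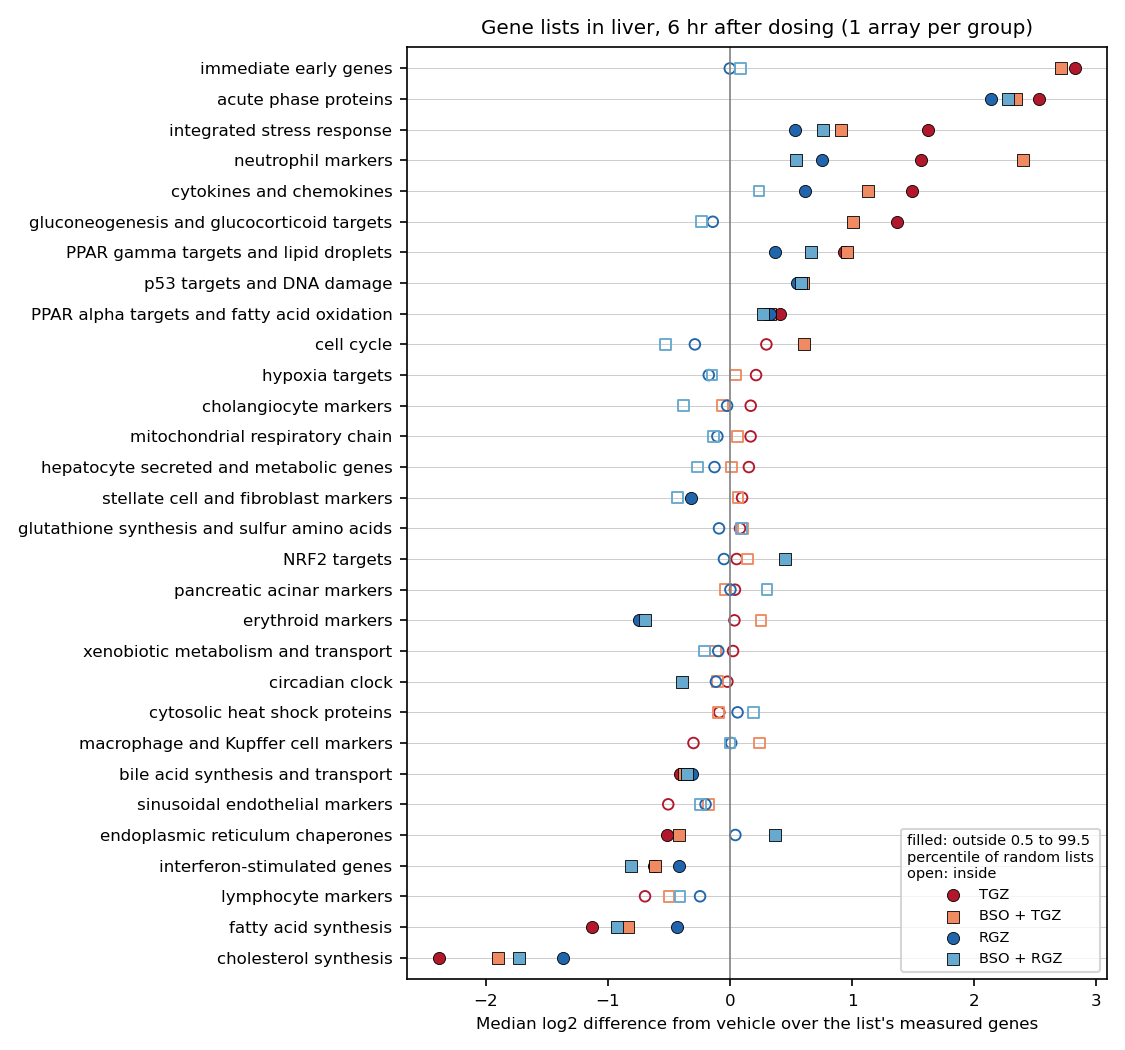
Median log2 difference from vehicle (horizontal axis) over the measured genes of 30 lists, for TGZ, BSO plus TGZ, RGZ and BSO plus RGZ. Filled symbols mark lists whose median was exceeded by, or exceeded, less than 0.5% of random lists matched on expression. Medians of immediate early genes are 2.83 and 2.71 with TGZ without and with BSO and 0.00 and 0.08 with RGZ without and with BSO. Acute phase proteins lie at 2.14 or more in all 4 groups, which are compared with the same vehicle array.

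The comparison of BSO plus TGZ with vehicle covers the same compound given with the inhibitor of glutathione synthesis. Cd14 was 156-fold higher, Saa1 103-fold, Arid5a 94.8-fold and Saa2 91.7-fold higher. Pdk4 was 85.6-fold higher, Rab30, a small GTPase of the Golgi, 77.2-fold and Atf3 74.8-fold higher. Il1r2 was at least 88.9-fold higher, and Hcar2, the niacin receptor gene, at least 5.64 higher on the log2 scale. Derl3 was 12.1-fold lower (9.15 to 15.9), Fam214a 9.55-fold, the steroid dehydrogenase gene Hsd3b5 9.17-fold and Cyp7a1 8.89-fold lower. Here 1781 genes were at least 2-fold higher and 1262 at least 2-fold lower than vehicle, 14.2% of genes with a value. Normexp gave 890 and 490, and spike-in scaling turned the balance (1393 and 1962).

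Immediate early genes had a median of 2.71 with BSO plus TGZ, with 14 of 17 higher, and Nr4a1 was 34.3-fold higher. Acute phase proteins had a median of 2.34 with 15 of 21 higher, Lcn2 at 68.7-fold. Cholesterol synthesis genes had a median of -1.90 with 16 of 19 lower, Sqle at 6.46-fold lower. Fatty acid synthesis genes had a median of -0.84 with 6 of 14 lower and 1 higher, Fasn at 4.42-fold lower. The integrated stress response had 9 of 18 members higher (median 0.91), with Chac1 at 22.6-fold. Cytokines and chemokines had 10 of 19 higher (median 1.13), neutrophil markers 9 of 13 (median 2.40), p53 targets 8 of 19 (median 0.60, with 1 lower) and lipid droplet and PPAR gamma genes 8 of 16 (median 0.96). Cdkn1a was 64.3-fold higher, Retnlg 37.8-fold and Cidec 38.9-fold. Gluconeogenesis and glucocorticoid targets had 7 of 12 higher and 2 lower (median 1.01), and PPAR alpha targets 8 of 24 higher (median 0.33). The PPAR alpha list no longer stood apart with the mean over each gene's probes (median 0.21, percentile 96.24), nor did interferon-stimulated genes with the mean in place of the median (mean -0.37, percentile 1.98). Interferon-stimulated genes (median -0.61, 3 of 16 lower and 1 higher), endoplasmic reticulum chaperones (median -0.42, 2 of 16 lower and 1 higher) and bile acid genes (median -0.38, 3 of 16 lower) were lower. Hmox1 was 40.4-fold and Srxn1 4.55-fold higher, although NRF2 targets did not stand apart as a list (median 0.14, 4 of 20 higher). Cell cycle genes were higher here (median 0.61, 4 of 11 higher and 1 lower), with cyclin E1 (Ccne1) at 3.93-fold, but that call was lost without the filter on dim probes (median 0.33, percentile 94.98) and with the mean in place of the median (percentile 95.79). It was also lost, at percentiles of 99.06 to 99.48, with median scaling, genes well above background on all 5 arrays, the submitters' filter and the deposited log2 table.

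The comparison of RGZ with vehicle shows the response to the related compound at the same dose and time. Saa1 was 85.1-fold higher with RGZ (64.5 to 112) and Saa2 74.1-fold. Saa3 was 40.6-fold higher (30.7 to 53.5), Lcn2 28.4-fold, Ccr8 17.8-fold, Cep55, a protein of cell abscission, 16.5-fold, the acute phase gene Orm3 15.1-fold and Steap4 10.8-fold higher. Bhlha15, a transcription factor of secretory cells, was at least 26.5-fold higher. Hsd3b5 was 14.0-fold lower (10.0 to 19.5), A1bg 9.45-fold, Dmbt1 5.15-fold and the nuclear receptor gene Esrrg 5.12-fold lower. The adipsin gene Cfd was at least 9.19-fold and the smooth muscle gene Cnn1 at least 6.27-fold lower, although Cnn1 was at -0.95 on the log2 scale with normexp background correction. In all, 352 genes were at least 2-fold higher and 354 at least 2-fold lower, 3.3% of genes with a value, and 49 and 21 differed by at least 4-fold. Normexp gave 135 and 89, spike-in scaling 452 and 259, and no filter on dim probes 1173 and 1635.

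Acute phase proteins were again higher with RGZ (median 2.14, 14 of 21 members) and cholesterol synthesis genes lower (median -1.37, 14 of 19 members). Sqle was 4.17-fold, Insig1 3.98-fold, Cyp51 3.24-fold and Idi1 3.20-fold lower. Immediate early genes did not stand apart (median 0.00, 2 of 15 higher), with Myc at 3.43-fold (0.67 on the log2 scale with normexp) and Jun at 2.42-fold. Of the integrated stress response, 4 of 18 members were higher (median 0.53), with the hepatokine gene Fgf21 at 6.83-fold and Chac1 at 5.64-fold. With normexp background correction that list no longer stood apart (median 0.14, percentile 98.63). Of 15 cytokine and chemokine genes 5 were higher (median 0.61), with Il1rn at 3.54-fold and Socs3 at 3.13-fold. Of 10 neutrophil markers 4 were higher (median 0.76), with S100a8 at 3.29-fold, a call that normexp also ended (median 0.18, percentile 99.43). PPAR gamma targets and lipid droplet genes had 4 of 14 higher and 1 lower (median 0.37). The lipolysis inhibitor gene G0s2 was 5.30-fold, Plin4 2.75-fold and Cidec 2.54-fold higher. PPAR alpha targets (median 0.32, 1 of 24 higher) and p53 targets (median 0.55, 1 of 19 higher and 1 lower) stood apart by small shifts of many members. Cdkn1a was 3.31-fold higher (0.77 on the log2 scale with the mean over its probes) and Bbc3 2.56-fold lower. Fatty acid synthesis genes (median -0.44, 1 of 14 lower and 1 higher), interferon-stimulated genes (median -0.42, 2 of 16 lower and 1 higher) and bile acid genes (median -0.32, 1 of 16 lower and 1 higher) were lower. Acss2 was 2.48-fold, Usp18 2.39-fold and Slco1a1 3.55-fold lower, while Gbp2 was 3.32-fold and Cyp7a1 2.59-fold higher. Erythroid markers were lower beside these (median -0.75, 1 of 6 past 2-fold, Slc4a1 at 2.45-fold), as were stellate cell and fibroblast markers (median -0.32, 1 of 11, Col3a1 at 2.07-fold). Slc4a1 was below 2-fold with normexp (-0.47 on the log2 scale), and Col3a1 with normexp (-0.90), the mean over its probes (-0.49) and spike-in scaling (-0.96). NRF2 targets had no member past 2-fold with RGZ (median -0.05), and endoplasmic reticulum chaperones had 1 of 16 higher (median 0.04).

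With BSO plus RGZ, Saa3 was 233-fold higher than with vehicle (177 to 307), Saa1 96.9-fold, Saa2 82.1-fold and Lcn2 59.2-fold. Ccr8 was 29.7-fold, Cep55 28.1-fold and Orm3 19.5-fold higher, and Bhlha15 at least 73.1-fold. Dmbt1 was 20.8-fold lower (15.7 to 27.5), the anion exchanger gene Slc26a4 11.4-fold, A1bg 9.56-fold, Hsd3b6 9.07-fold, Rgs16 8.81-fold and Insig1 8.49-fold lower. Hsd3b5 was at least 30.4-fold lower. The genes at least 2-fold different numbered 647 higher and 801 lower, 6.8% of genes with a value. The balance turned with median scaling (844 and 621), spike-in scaling (901 and 577) and normexp (280 and 248). NRF2 targets were higher as a list (median 0.45, 4 of 20 past 2-fold). Srxn1 was 4.35-fold, the carbonyl reductase gene Cbr3 3.03-fold, the thioredoxin reductase gene Txnrd1 2.68-fold and Hmox1 2.14-fold higher. Endoplasmic reticulum chaperones were also higher (median 0.37, 3 of 16), with Dnajb9 at 5.66-fold, Creld2 at 2.22-fold and Manf at 2.06-fold. The integrated stress response (median 0.76, 6 of 18 higher and 1 lower) included Fgf21 at 18.0-fold and Asns, asparagine synthetase, at 4.17-fold (0.98 on the log2 scale with normexp). With normexp background correction that list no longer stood apart (median 0.19, percentile 99.34), nor did neutrophil markers (median 0.16, percentile 98.58). Acute phase proteins (median 2.28, 16 of 21 higher), p53 targets (median 0.58, 6 of 19 higher and 1 lower, Cdkn1a at 7.49-fold), PPAR gamma targets and lipid droplet genes (median 0.66, 4 of 14 higher and 1 lower, Cidec at 5.36-fold), PPAR alpha targets (median 0.27, 1 of 24 higher) and neutrophil markers (median 0.54, 4 of 12 higher, S100a8 at 4.46-fold) were higher. Cholesterol synthesis genes (median -1.73, 14 of 19 lower), fatty acid synthesis genes (median -0.92, 7 of 14 lower and 1 higher), interferon-stimulated genes (median -0.81, 7 of 16 lower and 1 higher), bile acid genes (median -0.35, 2 of 16 lower) and erythroid markers (median -0.70, none past 2-fold) were lower. Thrsp was 3.69-fold and Ifit1 3.37-fold lower. Circadian clock genes had a median of -0.39 with none of 13 past 2-fold, and 5 alternatives ended that call (percentiles 0.61 to 4.14): normexp, the mean of the list, the mean over each gene's probes, no filter on dim probes, and only genes well above background on all 5 arrays. Immediate early genes (median 0.08, 3 of 15 higher and 1 lower) and cytokines and chemokines (median 0.24, 4 of 14 higher) did not stand apart, although the cytokine list did with the mean in place of the median (mean 0.51, percentile 99.93).

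**Figure D2:**
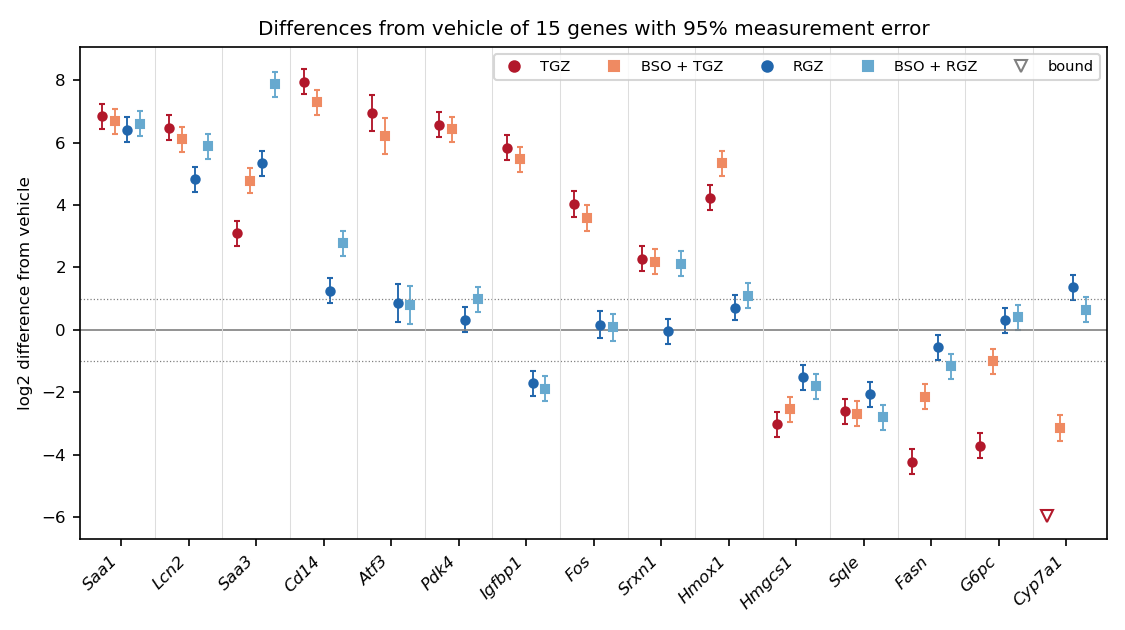
Log2 difference from vehicle (vertical axis) of 15 genes on the 4 arrays of treated livers, with bars for the 95% interval of spot measurement error, dotted lines at 2-fold and an open triangle for a bound. Saa1 is 85.1-fold or more above vehicle in all 4 groups, which are compared with the same vehicle array. Its signals in the treated groups lie above the spike-in range, so its folds could be lower bounds. Cd14, Atf3, Pdk4, Igfbp1 and Fos separate TGZ from RGZ.

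TGZ and RGZ share the thiazolidinedione head group and differ in the rest of the molecule: TGZ carries a chroman group like that of vitamin E, and RGZ a pyridyl-amino-ethoxy chain. At the matched dose of 300 mg/kg and 6 hr, Igfbp1 was 188-fold higher with TGZ than with RGZ (143 to 249). Cd14 was 104-fold, Pdk4 76.0-fold, the glycogen-targeting phosphatase subunit gene Ppp1r3g 70.8-fold, Atf3 66.9-fold and Arid5a 57.2-fold higher. Hilpda, a lipid droplet protein that inhibits lipolysis, was 56.2-fold higher, and Thbs1 at least 56.9-fold. Fam89a was 35.6-fold lower with TGZ (26.2 to 48.4), Dclk3 29.9-fold, Wnt5b 22.3-fold, the potassium channel gene Kcnj10 21.5-fold and Angptl8, an inhibitor of lipoprotein lipase, 20.6-fold lower. Cyp7a1 was at least 163-fold lower with TGZ than with RGZ. Between the compounds 1984 genes were at least 2-fold higher and 1808 at least 2-fold lower with TGZ, 18.0% of genes with a value, where measurement error alone would give about 8.4. Normexp background correction gave 951 higher and 842 lower, and spike-in scaling 972 and 4546.

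By list, TGZ exceeded RGZ in immediate early genes (median 2.62, 16 of 17 members), with Btg2 at 50.5-fold. The same held for gluconeogenesis and glucocorticoid targets (median 1.41, 7 of 12 higher and 2 lower), with Irs2 at 10.9-fold higher and G6pc at 16.2-fold lower, and for the integrated stress response (median 1.17, 9 of 18), with Ddit4 at 18.4-fold. Neutrophil markers (median 1.72, 8 of 13, Retnlg at 19.2-fold), cytokines and chemokines (median 0.94, 8 of 17, Cxcl1 at 21.2-fold), erythroid markers (median 0.88, 2 of 6) and PPAR gamma targets and lipid droplet genes (median 0.56, 6 of 15 higher and 1 lower, Cidec at 21.1-fold) were also higher with TGZ. Cholesterol synthesis (median -0.88, 7 of 19 lower and 1 higher), fatty acid synthesis (median -0.52, 5 of 14 lower and 1 higher) and endoplasmic reticulum chaperones (median -0.52, 3 of 16 lower) were lower with TGZ. Mvd was 5.02-fold, Fasn 12.7-fold and Sdf2l1 3.17-fold lower. The neutrophil and erythroid calls were lost when only genes well above background on all 5 arrays were kept (percentiles 95.94 and 99.34). The erythroid call was also lost after quantile normalization (percentile 99.26), without the filter on dim probes (99.30) and with the submitters' filter (99.42).

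The compounds did not differ by more than random matched lists in acute phase proteins (median difference 0.44, percentile 99.24), PPAR alpha targets (0.04), p53 targets (0.18), NRF2 targets (0.18), xenobiotic metabolism and transport (0.19), hepatocyte secreted and metabolic genes (0.34) or respiratory chain genes (0.30). Single members of these lists still differed. Of p53 targets, 8 of 19 were at least 2-fold higher with TGZ and 2 lower, Cdkn1a at 25.0-fold higher, and with the mean in place of the median that list did stand apart (mean 1.16, percentile 100). Of NRF2 targets, 4 of 20 were higher and 1 lower. The acute phase list stood apart without the filter on dim probes (percentile 99.64) and with the mean over each gene's probes (99.96). Within the acute phase list Saa3 was 4.76-fold lower and Lcn2 3.14-fold higher with TGZ, and Hmox1 was 11.5-fold and Sult1e1, an estrogen sulfotransferase, 6.79-fold higher. Of the genes at least 2-fold from vehicle, 190 were higher with both compounds and 158 lower with both, against 28.0 and 34.6 for independent lists. Independence is not what unchanged groups give here, since both comparisons use the vehicle array. Simulated unchanged groups shared a mean of 0.31 genes. The simulation holds spot measurement error only and leaves out deviations of the vehicle pool. It therefore does not show how many shared genes the common vehicle pool would give. In the opposite direction, 17 were higher with TGZ and lower with RGZ, and 16 were lower with TGZ and higher with RGZ. Across 18483 genes the differences from vehicle of the compounds correlated with r = 0.388 (rho 0.323). Both use the same vehicle array, and simulated unchanged groups gave r = 0.498. The covariance was 0.14 against 0.02 in the simulation, and part of the excess may come from the shared vehicle array. Genes are not independent replicates.

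Addition of BSO to TGZ raises the question of how the response differed with this inhibitor of glutathione synthesis, although these data do not measure glutathione. The replication-dependent histone genes Hist2h3c1 and Hist2h3c2 were 9.27-fold (5.87 to 14.6) and 8.26-fold higher with BSO plus TGZ than with TGZ, although their probes can share sequence with other histone genes. Fam89a was 7.54-fold, Kcnj10 6.84-fold, G6pc 6.52-fold (4.94 to 8.60), Angptl8 5.36-fold, Prok1 5.01-fold and Anks4b 4.41-fold higher. Gsx1 was 9.04-fold lower (6.28 to 13.0) and the thromboxane receptor gene Tbxa2r 5.91-fold lower. Adam12 was 3.41-fold lower, but its log2 difference was -0.08 with the mean over its probes and -0.94 with normexp. With normexp background correction the log2 differences of Kcnj10, Prok1 and Anks4b were 0.90, 0.82 and 0.86, below 2-fold. The genes at least 2-fold different numbered 326 higher and 103 lower, 2.1% of genes with a value. They numbered 50 and 18 with normexp, 672 and 42 with spike-in scaling and 1374 and 1260 with no filter on dim probes.

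Several list medians moved by less than 2-fold between BSO plus TGZ and TGZ. Immediate early genes were lower with BSO plus TGZ (median -0.45, 1 of 17 past 2-fold, Btg2 at 2.18-fold), as was the integrated stress response (median -0.44, 1 of 18, the folate enzyme gene Mthfd2 at 2.14-fold). Acute phase proteins had a median of -0.19 with 1 of 21 past 2-fold, Saa3 at 3.23-fold higher, and xenobiotic metabolism genes a median of -0.22. With spike-in scaling these medians were 0.07 and 0.04. Gluconeogenesis and glucocorticoid targets had a median of -0.27, but a mean of 0.04, with G6pc and Tsc22d3 6.52-fold and 2.01-fold higher. Macrophage and Kupffer cell markers (median 0.45) and sinusoidal endothelial markers (median 0.40) were higher with BSO plus TGZ with no member past 2-fold. Marco was 1.88-fold, C1qa 1.67-fold, Oit3 1.76-fold and Kdr 1.70-fold higher. Cell cycle genes (median 0.44), erythroid markers (median 0.29), cholesterol synthesis genes (median 0.24), NRF2 targets (median 0.17) and endoplasmic reticulum chaperones (median 0.09) were also higher. Among NRF2 targets Osgin1 was 2.91-fold and Hmox1 2.14-fold higher, and Mvd of the cholesterol list was 1.95-fold higher. In lists that did not stand apart, Fasn was 4.25-fold, Nr0b2 3.19-fold, Per2 2.89-fold and Hlf 2.41-fold higher, and Cyp7a1 was at least 7.09-fold higher. The fatty acid synthesis, bile acid and clock lists stood apart with the mean in place of the median (percentiles 99.86, 99.92 and 99.85). With normexp the log2 differences of Nr0b2, Hlf, Cyp7a1 and Mthfd2 were 0.67, 0.98, 0.83 and -0.41. With the mean over its probes Per2 was at 0.92, Tsc22d3 at 0.82 and Mthfd2 at -0.55, with spike-in scaling Btg2 was at -0.87 and Mthfd2 at -0.83, and with median scaling Tsc22d3 was at 0.94. With the mean in place of the median, 5 lists besides the gluconeogenesis list no longer kept their calls: acute phase proteins (percentile 39.09), xenobiotic metabolism (2.86), endoplasmic reticulum chaperones (95.29), erythroid markers (98.55) and cell cycle genes (98.99). The acute phase median was 0.00 after quantile normalization (percentile 18.70), the chaperone call was lost with the mean over each gene's probes (98.50), and the erythroid call with genes well above background on all 5 arrays (99.32) or no filter (99.45).

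With BSO plus RGZ, 110 genes were at least 2-fold higher and 152 lower than with RGZ, 1.2% of genes with a value. Normexp gave 22 and 21, no filter on dim probes 1125 and 1354, and the balance turned with median scaling (154 and 101) and quantile normalization (133 and 110). Saa3 was 5.75-fold higher (4.35 to 7.58), Srxn1, which repairs oxidised peroxiredoxins, 4.51-fold (3.42 to 5.95), Pak3 3.74-fold and Derl3 3.64-fold higher. Dmbt1 was 4.03-fold lower (3.05 to 5.33), Nrep 3.73-fold, Slc26a4 3.41-fold and Hsd3b6 3.32-fold lower. Pak3 differed by 0.45 on the log2 scale with the mean over its probes, and Pak3, Slc26a4 and Hsd3b6 by 0.69, -0.59 and -0.71 with normexp background correction. NRF2 targets were higher as a list (median 0.55), with 4 of 20 past 2-fold and none lower. Besides Srxn1 these were Cbr3 at 2.77-fold, Txnrd1 at 2.09-fold and Gclc, the catalytic subunit of the enzyme BSO inhibits, at 2.04-fold. Endoplasmic reticulum chaperones were higher too (median 0.40, 1 of 16 past 2-fold), with Sdf2l1 at 2-fold and Creld2 at 1.77-fold. The integrated stress response (median 0.18, Fgf21 at 2.63-fold and Asns at 2.49-fold), acute phase proteins (median 0.19), PPAR gamma targets and lipid droplet genes (median 0.19), p53 targets (median 0.17) and neutrophil markers (median 0.27) were higher by small amounts. Cholesterol synthesis (median -0.31, Insig1 at 2.13-fold lower), fatty acid synthesis (median -0.37, Srebf1 at 2.61-fold lower) and interferon-stimulated genes (median -0.33) were lower. Circadian clock genes (median -0.22), cytokines and chemokines (median -0.21, Cxcl10 at 2.06-fold lower), xenobiotic metabolism (median -0.16), gluconeogenesis and glucocorticoid targets (median -0.16) and PPAR alpha targets (median -0.11) were lower by small amounts as well. Genes of glutathione synthesis and sulfur amino acids did not stand apart after BSO with either compound (medians -0.06 with TGZ and 0.09 with RGZ).

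Many of these small differences of lists between BSO plus RGZ and RGZ depended on the processing. Neutrophil markers no longer stood apart with normexp (percentile 97.04), genes well above background on all 5 arrays (91.63) and the submitters' filter (93.91). The integrated stress response lost its call with genes well above background on all 5 arrays (99.34) and the mean over each gene's probes (98.47). With that mean, PPAR gamma targets (93.44) and p53 targets (99.36) lost theirs, as they did with the submitters' filter (99.47, PPAR gamma) and with quantile normalization and the deposited log2 table (99.42 and 99.49, p53). Cytokines and chemokines lost theirs with normexp (2.15), quantile normalization (1.68), no filter (0.54) and the submitters' filter (1.18). With the mean in place of the median, PPAR alpha targets (26.51), gluconeogenesis and glucocorticoid targets (7.73), xenobiotic metabolism (5.36) and circadian clock genes (1.07) no longer stood apart. PPAR alpha targets also lost their call with quantile normalization (0.73) and the deposited log2 table (0.58), and gluconeogenesis targets with normexp (0.60). Among single genes, normexp gave log2 differences of 0.97 for Gclc, 0.97 for Sdf2l1, 0.75 for Asns, -0.84 for Insig1 and -0.76 for Cxcl10. Median scaling gave -0.96 for Cxcl10.

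**Figure D3:**
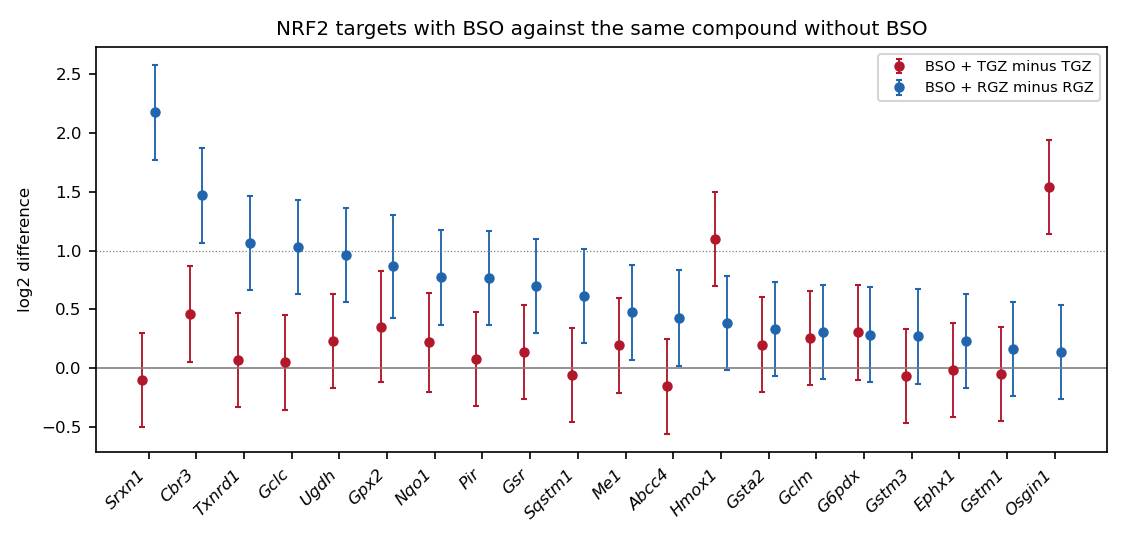
Log2 difference (vertical axis) of 20 NRF2 targets between livers given BSO and the same compound and livers given the compound alone, with bars for the 95% interval of spot measurement error and a dotted line at 2-fold. With RGZ the list's median is 0.55 and Srxn1 lies at 2.17, and with TGZ the median is 0.17 and Srxn1 lies at -0.10.

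Gene by gene, the BSO effects with each compound did not correlate. Across 18483 genes the BSO effect with TGZ and the BSO effect with RGZ, which have no array in common, correlated with r = -0.01 (rho 0.003). Here 7 genes were at least 2-fold higher with BSO in both and 2 at least 2-fold lower in both, against 1.1 and 0.4 for independent lists, while 7 were higher with BSO in the TGZ pair and lower in the RGZ pair and 0 the reverse. By list, 4 stood apart in the same direction with both compounds: NRF2 targets (0.17 with TGZ and 0.55 with RGZ) and endoplasmic reticulum chaperones (0.09 and 0.40) were higher, and xenobiotic metabolism (-0.22 and -0.16) and gluconeogenesis and glucocorticoid targets (-0.27 and -0.16) lower. With the mean in place of the median only NRF2 targets kept the call in the TGZ pair, where the other percentiles were 95.29 for chaperones, 2.86 for xenobiotic metabolism and 92.06 for gluconeogenesis targets (mean 0.04). The xenobiotic median of that pair was 0.04 with spike-in scaling. The BSO effect was at least 2-fold higher with TGZ than with RGZ for 406 of 18662 genes and at least 2-fold lower for 187. This balance was not recalculated with other scalings, which move the BSO effects unequally. Median scaling moved the median of all genes by -0.07 in the TGZ pair and 0.08 in the RGZ pair, and spike-in scaling by 0.26 and 0.04. At the same time the difference between the compounds kept its shape: TGZ minus RGZ without BSO and with BSO correlated with r = 0.866 (rho 0.812), with a slope of 0.72 for the values with BSO on those without. These differences share no array, so simulated unchanged groups with independent errors had to give a value near 0 (r = 0.0009).

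**Figure D4:**
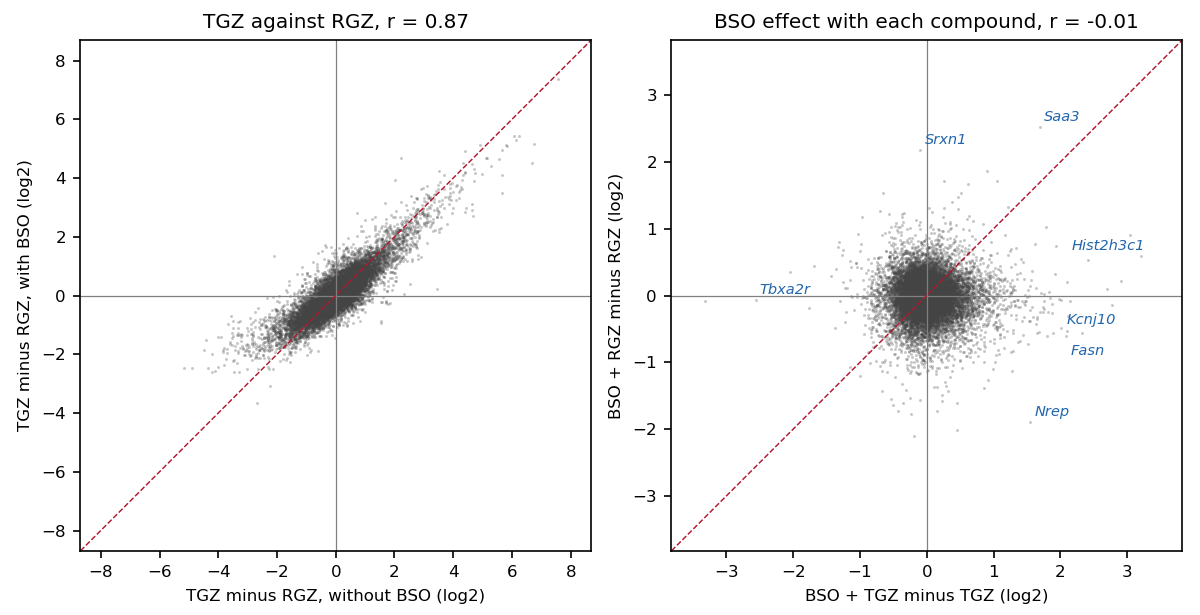
Each point is 1 of 18483 genes well above background on all 5 arrays, plotted as log2 differences with the line of equality dashed. The difference between TGZ and RGZ is similar without and with BSO (r = 0.866), whereas the BSO effects with each compound show no correlation (r = -0.01).

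With BSO given to both, Igfbp1 was 164-fold higher with TGZ than with RGZ (124.5 to 217), Pdk4 43.4-fold, Atf3 43.0-fold, Ppp1r3g 39.0-fold and Hilpda 35.0-fold. Bhlha15 was 49.1-fold lower (31.3 to 77.0), Cyp7a1 13.8-fold, Derl3 12.6-fold, Mycl 8.72-fold and Saa3 8.46-fold lower. A total of 1775 genes were at least 2-fold higher and 1124 at least 2-fold lower, and 1278 and 862 were so both without and with BSO. The balance turned with median scaling (1370 higher and 1656 lower) and spike-in scaling (1071 and 2396). Normexp gave 739 and 445, and no filter on dim probes 3602 and 2072. Immediate early genes (median 2.47, 14 of 17), neutrophil markers (median 1.82, 7 of 13), gluconeogenesis and glucocorticoid targets (median 1.01, 6 of 12 higher and 1 lower), cell cycle genes (median 1.13, 6 of 11 higher and 1 lower), erythroid markers (median 0.94, 3 of 6), cytokines and chemokines (median 0.75, 7 of 19) and PPAR gamma targets and lipid droplet genes (median 0.55, 5 of 16 higher and 1 lower) were higher with TGZ. The integrated stress response (median 0.40, 5 of 18 higher and 2 lower) and macrophage and Kupffer cell markers (median 0.38, 4 of 16) were higher by less, and neither stood apart after quantile normalization (percentiles 99.49 and 99.46) or with normexp (98.74 and 99.29), nor did the macrophage list with genes well above background on all 5 arrays (99.26). With only those genes the cell cycle list had a median of 0.37 and no longer stood apart (percentile 89.22), nor did it with the submitters' filter (median 0.37, percentile 90.0) or the mean in place of the median (percentile 99.0). Endoplasmic reticulum chaperones (median -0.75, 5 of 16 lower) and NRF2 targets (median -0.31, 1 of 20 higher) were lower with TGZ, although Hmox1 was 18.9-fold higher and the mean of the NRF2 list was -0.01 (percentile 23.95), which did not stand apart. Cholesterol synthesis genes no longer differed beyond random lists (median -0.24, percentile 5.74), nor did fatty acid synthesis genes (median 0.02).

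Most lists of markers of other cell types did not stand apart from vehicle. Sinusoidal endothelial markers had a median of -0.51 with TGZ, which did not stand apart (percentile 2.07), with 5 of 11 at least 2-fold lower and 2 higher. Tek was 4-fold (-0.60 on the log2 scale with normexp) and the vascular endothelial growth factor receptor gene Kdr 3.84-fold lower, and Lyve1 was 13.4-fold higher. Macrophage and Kupffer cell markers had medians of -0.30 with TGZ, 0.24 with BSO plus TGZ, 0.01 with RGZ and 0.00 with BSO plus RGZ, and stood apart in none, although with the mean in place of the median they did with BSO plus TGZ (mean 0.74, percentile 99.82). Marco, a scavenger receptor gene, was 3.43-fold higher with RGZ and 3.59-fold higher with BSO plus RGZ. Lymphocyte markers had medians of -0.70, -0.50, -0.25 and -0.41 in the same order and did not stand apart, except with BSO plus TGZ with the mean over each gene's probes (median -0.61, percentile 0.40). Cholangiocyte markers (medians 0.17, -0.06, -0.02 and -0.38) and pancreatic acinar markers (medians 0.04, -0.04, 0.00 and 0.30) did not stand apart, but Sox9 was 13.4-fold higher with TGZ and Krt19 5.55-fold lower with BSO plus RGZ. Stellate cell and fibroblast markers with TGZ had a median of 0.10, with the retinol-storing enzyme gene Lrat 4.62-fold lower (-0.95 on the log2 scale with normexp). Cytosolic heat shock proteins (medians -0.09, -0.09, 0.06 and 0.19), hypoxia targets (medians 0.21, 0.05, -0.17 and -0.15) and xenobiotic metabolism and transport (medians 0.02, -0.12, -0.10 and -0.21) did not stand apart from vehicle in any group. The hypoxia list did with the mean in place of the median with TGZ (mean 1.13, percentile 99.90) and BSO plus TGZ (0.87, 99.78). Bag3 was 3.43-fold higher with TGZ, the glucose transporter gene Slc2a1 4.07-fold, and Sult1e1 8.68-fold.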

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

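The genes and lists of the next paragraph are given because the BSO effect with TGZ (BSO plus TGZ minus TGZ) and the BSO effect with RGZ (BSO plus RGZ minus RGZ) pointed in opposite directions. None of these differences was tested, since each effect rests on 1 array against 1 array. The 3 patterns weighed after them come from other comparisons. Of the tests below, the comparison with lists of like expression, those with spike-in scaling, and those of chance differences between pools and of the vehicle array were chosen after the result was seen.

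Nrep was 1.55 higher with BSO on the log2 scale with TGZ and -1.90 with RGZ, a difference of 3.45. Kcnj10 (difference 2.92), Prok1 (2.89), Fasn (2.69) and Wnt5b (2.63) were higher with BSO in the TGZ pair and lower with BSO in the RGZ pair. Srxn1 (difference -2.27), Cd14 (-2.19), Bhlha15 (-2.07), Ier3 (-1.97) and Mthfd2 (-1.86) were lower with BSO in the TGZ pair, higher in the RGZ pair. However, the TGZ value of Srxn1, -0.10, and the RGZ value of Kcnj10, -0.14, lie within their measurement error of 0. The TGZ value of Bhlha15 was -0.60 and the error SD of its difference 0.43, so its direction with TGZ is uncertain. With normexp background correction the difference of Mthfd2 was -0.73. By list, the integrated stress response (difference -0.63) and acute phase proteins (-0.35) were lower with BSO in the TGZ pair and higher in the RGZ pair, and cholesterol synthesis genes (0.65) the reverse. Spike-in scaling turns the acute phase median of the TGZ pair to 0.07, so its opposition is lost there.

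The first pattern is that differences from vehicle were smaller with BSO plus TGZ than with TGZ alone. If noise of the TGZ array made its differences look large, genes chosen only for their difference with BSO plus TGZ should not lie farther out with TGZ, but 76.5% of 2316 such genes did. With spike-in scaling 69.9% of 2582 did, but the genes higher and lower with BSO plus TGZ parted. Among those lower, 82.0% lay farther out with TGZ and 92.4% with spike-in scaling. Among those higher, 72.9% did and only 39.3% with spike-in scaling, which also gave more genes at least 2-fold higher with BSO plus TGZ (1393) than with TGZ (1210). For higher genes the pattern thus depends on the scaling. A compressed range of the BSO plus TGZ array is argued against by the spike-in RNA, whose signal on that array followed the TGZ array with a slope of 0.992 (0.989 to 0.997 leaving out 1 of 8 probes). An effect of BSO on the response to TGZ may stand behind the pattern, but so may differences between the pools of animals, which 1 array per group cannot separate.

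The second pattern is the larger number of genes at least 2-fold from vehicle with TGZ than with RGZ. After removal of a trend with probe GC content the ratio was 6.38, after removal of a trend with signal 6.66, and in the 5583 genes of highest signal 5.91 (703 genes against 119), so none of these could account for it. Chance differences between pools are argued against by TGZ minus RGZ without and with BSO, which have no pool in common and correlated with r = 0.866. Both TGZ groups also had more genes past 2-fold from vehicle (4167 and 3043 with BSO) than both RGZ groups (706 and 1448). Noise of the vehicle array enters the comparisons of TGZ and of RGZ with vehicle alike. Without that array, 3792 genes were at least 2-fold different between TGZ and RGZ and 2899 with BSO in both. These counts follow largely from those against vehicle, so they are not a separate test. The vehicle array also correlated with the RGZ array (0.990) more closely than the TGZ array did (0.958). A stronger response to TGZ at this dose and time is a candidate explanation, and handling that the TGZ groups had in common stays open.

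The third pattern is that NRF2 targets were higher with BSO plus RGZ than with RGZ alone. Faults of single probes are argued against by the other 8 probes of 6 of these genes, which had a median of 0.66 with 7 above 0. Random lists of genes of like expression had a median of 0.0091, where that of the NRF2 targets was 0.55. The list was called against these same random lists, so this is not a separate test of a shift of all such genes. Spike-in scaling moves the random lists and the NRF2 list together (0.05 and 0.58) and adds no test either. The position of the array on the slide stays open, since 0 arrays of this group lay at a second position and position and group cannot be told apart. Differences between the pools of animals stay open as well, since 1 array per group cannot separate them from BSO. A response to lower glutathione may be one hypothesis, but these data do not measure glutathione. Replicate pools, also of livers given BSO alone, would be needed to examine it.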

How the results depend on the processing

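Spike-in scaling was chosen after the data were seen, and the other alternatives before. All 2920 recalculated differences of single genes that were at least 2-fold kept their direction, and 55 of them fell below 2-fold, 42 with normexp background correction. Of smaller differences plotted or named, 7 passed 2-fold and 2 changed sign, Fos with BSO plus RGZ (-0.018 with normexp) and Srxn1 with RGZ (0.038 with spike-in scaling). Of list medians, 970 of 1040 recalculated for lists that stood apart kept both direction and call, 66 lost the call without changing sign and 4 reversed. Median and spike-in scaling move a list and its random lists alike, so calls could hardly change there. Lists that did not stand apart stayed so in 1313 recalculations and did in 47. Gene counts moved by more than 1.5 times in 54 of 160 recalculations. Genes not well above background on both arrays have bounds only, and the dim ones decide how counts change with the filter. Except where stated the cause was not tested.

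With normexp background correction, genes at least 2-fold higher and lower numbered 1104 and 909 for TGZ against vehicle, 890 and 490 for BSO plus TGZ, 135 and 89 for RGZ, 280 and 248 for BSO plus RGZ, 50 and 18 for BSO plus TGZ against TGZ, 22 and 21 for BSO plus RGZ against RGZ, 951 and 842 for TGZ against RGZ, and 739 and 445 for TGZ against RGZ with BSO in both. Normexp adds an offset to every signal, which pulls log2 differences of dim probes toward 0. The percent of called genes that were higher became 60.3 for RGZ (49.9 before). With no filter on dim probes they numbered, in the same order, 3682 and 3206, 3176 and 2398, 1173 and 1635, 1567 and 2336, 1374 and 1260, 1125 and 1354, 3748 and 2777, and 3602 and 2072, as probes near background enter the counts, and 52.2% were higher for BSO plus TGZ against TGZ (76.0 before). The correlation of TGZ minus RGZ without and with BSO was then 0.63. With only genes well above background on all 5 arrays, RGZ against vehicle had 233 higher and 209 lower, BSO plus TGZ against TGZ 202 and 32 (86.3% higher), and BSO plus RGZ against RGZ 47 and 70, since bounds and genes dim on arrays outside the comparison are left out. The submitters' probe filter, which also leaves out bounds, gave 209 and 52 for BSO plus TGZ against TGZ and 68 and 88 for BSO plus RGZ against RGZ. The size rule with measurement error gave 54 and 95 lower genes for these comparisons, and median scaling 101 lower for BSO plus RGZ against RGZ. Among genes above the median of mean signal the correlation of TGZ and RGZ effects was 0.45. The mean in place of the median gave 0.044 for gluconeogenesis and glucocorticoid targets in BSO plus TGZ against TGZ.

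Spike-in scaling moved the median of all genes by -0.45 for TGZ against vehicle, -0.19 for BSO plus TGZ, 0.13 for BSO plus RGZ, 0.26 for BSO plus TGZ against TGZ, -0.54 for TGZ against RGZ and -0.32 for TGZ against RGZ with BSO in both. By this construction it gave 1210 higher and 4249 lower for TGZ against vehicle, 1962 lower for BSO plus TGZ, 672 higher and 42 lower for BSO plus TGZ against TGZ, 972 and 4546 for TGZ against RGZ, and 1071 and 2396 with BSO in both. Medians of PPAR alpha targets with TGZ (-0.043), and of acute phase proteins (0.071) and xenobiotic metabolism (0.036) in BSO plus TGZ against TGZ, changed sign. Relative to the shift of all genes they kept their calls, with percentiles of 99.94, 0.34 and 0.02. The percent of called genes that were higher became 22.2 for TGZ (51.5 before), 41.5 for BSO plus TGZ (58.5), 63.6 for RGZ (49.9), 61.0 for BSO plus RGZ (44.7), 94.1 for BSO plus TGZ against TGZ (76.0), 17.6 for TGZ against RGZ (52.3) and 30.9 with BSO in both (61.2). Median scaling moved the median of all genes by 0.10 for BSO plus RGZ and -0.15 for TGZ against RGZ with BSO in both. It gave 57.6% higher for BSO plus RGZ, 64.1% for BSO plus TGZ against TGZ, 60.4% for BSO plus RGZ against RGZ (42.0 before) and 45.3% for TGZ against RGZ with BSO in both. Quantile normalization gave 54.7% for BSO plus RGZ against RGZ.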

Other observations

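The families in this part, and the tests of them, were chosen after the values of all genes were seen. Steroid dehydrogenases of the Hsd3b family were lower in every treated group, with medians over 6 genes of -2.19 with TGZ, -1.92 with BSO plus TGZ, -1.33 with RGZ and -2.88 with BSO plus RGZ. These medians share the vehicle array and are not independent of each other. Against RGZ alone, BSO plus RGZ had a median of -1.49 with 5 of 6 genes at least 2-fold lower, and these directions held under median, quantile and spike-in scaling. Major urinary proteins had a median over 12 genes of -0.56 with RGZ and -0.76 with BSO plus RGZ. With TGZ their median was 0.18 and turned to -0.29 after quantile normalization and -0.27 with spike-in scaling. Probes of both families can share sequence.

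Kruppel-like factors, regulators of growth and metabolism, had a median of 0.83 with TGZ, with 5 of 13 at least 2-fold higher and 1 lower. Klf6 was 3.77 higher on the log2 scale, Klf4 2.52 and Klf11 1.91. Dual-specificity phosphatases, which dampen MAP kinase signalling, had a median of 0.60 with TGZ, with 7 of 18 higher and 3 lower, Dusp8 at 4.51 and Dusp5 at 3.67. With RGZ the medians were -0.24 and -0.10, and with spike-in scaling the TGZ medians of 0.38 and 0.16 stayed above 0. Clustered histone genes had 9 of 44 members at least 2-fold lower and 1 higher with TGZ (median -0.20). Hist2h3c1 was -3.75, Hist2h2be -3.46 and Hist1h4i -2.59. With spike-in scaling 14 of the 44 histone genes were at least 2-fold lower and 1 higher with TGZ (median -0.65).

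The spike-in RNA lay above the 75th percentile of liver probes by 0.44 more with TGZ than with vehicle and by 0.16 more with BSO plus TGZ, while RGZ and BSO plus RGZ differed by -0.09 and -0.11. The unscaled spike-in signal differed from vehicle by 0.05, 0.04, 0.08 and -0.06 in the same order. No explanation of this was tested.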
